A study of Mus musculus with 2 samples.

How the data were processed

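Small RNA from mouse embryonic facial prominence at embryonic day 15.5 was profiled by microRNA sequencing in 2 biological replicates. Replicate 1 pooled tissue from 78 embryos and replicate 2 from 62 embryos, both of strain B6NCrl with males and females mixed. The labels give a library size range below 30, without a unit. The labels number the samples as biological replicates and give each its own pool of embryos, so the spread between them covers dissection, pooling, library preparation and sequencing together. All samples belong to 1 group, and the comparison that the design allows is replicate against replicate.

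The authors deposited raw read counts per miRNA gene for each library, on the mm10 build with the GENCODE M4 annotation, per the labels and the deposited file list. Each table holds 1973 genes with 3 counts per gene, which are reads on either strand, on the strand of the gene and on the opposite strand. Separate lines count unmapped reads, reads that mapped to several places, reads outside the annotated genes and ambiguous reads. Reads that mapped to several places were not given to a gene in the deposited counts, so hairpins with near-identical copies can carry fewer counts than their transcripts produced, and their values are uncertain. The aligner and the counting program are not given in the sources used here.

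Gene names, positions and host genes were taken from GENCODE M21, a later annotation of the same build (GRCm38, equal to mm10), matched by gene identifier without its version. A symbol was found for 1894 of the 1973 genes, and 1815 had the same identifier version. Positions are 1-based. A gene was called exonic or intronic by overlap with another gene on the same strand. Hairpins that share a stretch of 20 bases with another miRNA hairpin were marked, which took in 929 genes.

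The counts on either strand were used throughout, and the other columns served as alternatives. Lines that name no gene stayed out of library sizes. Counts were scaled with TMM factors in edgeR 4.0.16 (R 4.3.3) and given as CPM, the unit of all levels, with mean and SD over the 2 replicates. A gene with at least 10 reads in each library counted as detected, and a gene with at most 3 reads in each counted as at the floor. Shares of counts carry 95% exact Clopper-Pearson intervals. These intervals and the floors cover counting error only, since reads counted without molecular identifiers are not independent molecules, and the labels name no such identifiers.

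Each detected gene was compared between the libraries by a two-sided exact binomial test of its reads against the ratio of effective library sizes, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. This test compares 2 libraries and covers counting error only, because 1 library against 1 leaves no residual degrees of freedom. An exact permutation of 2 libraries cannot give a p below 0.5. The variation between replicates was described by the edgeR common dispersion, with an SD from 100 bootstrap draws over genes, and by the log2 ratio of CPM in replicate 2 over replicate 1. For gene lists, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. The random lists took no account of genomic linkage, so percentiles of lists made of neighbouring genes are not those of independent genes.

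The groups, the tests, the filters, the gene lists and the alternatives were chosen before the data were examined. Named genes followed a rule: the 20 genes with the highest mean CPM, the 5 genes with the largest log2 ratio in each direction among those past the threshold with at least 50 reads on average, and up to 4 members of each list with the highest mean CPM. Genes named outside this rule are marked as chosen after their values were seen. Alternatives were total-count scaling, size factors from DESeq2 1.42.0, no filter or a filter of 100 reads, the other strand columns, summed copies of a mature miRNA, each replicate left out, and the most abundant gene left out of the totals.

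The test was checked on simulated data drawn from the real means and library sizes of replicate 2 against replicate 1. With counting noise only, it called 88% of 50 genes changed by 1.5-fold, 92% of 50 genes changed by 2-fold and 8.33% of 156 unchanged genes. With the estimated dispersion between replicates added, it called 51.0% of 155 unchanged genes, so a call marks a difference between these libraries and not one between populations. Tables were handled in Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.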

Results

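MicroRNA sequencing was used to profile the embryonic facial prominence, the tissue that forms the face and jaws, in mice at embryonic day 15.5. There was 1 group of 2 biological replicates, a pool of 78 embryos (replicate 1) and a pool of 62 embryos (replicate 2). The libraries held 5840705 reads in replicate 1 and 14085643 reads in replicate 2. Reads assigned to miRNA genes made up 48.2% ± 3.89 of the reads (SD, n = 2), with 2978463 in replicate 1 and 6408008 in replicate 2. A further 30.2% ± 0.649 mapped to several places, 19.0% ± 3.96 were unmapped and 2.60% ± 0.576 fell outside the annotated genes (SD, n = 2). Of 1973 miRNA genes, 333 had at least 10 reads in both libraries, and 1463 had at most 3 reads in each, including 1265 with no read in either. A count of 3 reads corresponds to 1.00 CPM in replicate 1 and 0.470 CPM in replicate 2. A gene at or below this level in both libraries counted as at the floor.

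The miRNA reads mapped to 1 place were dominated by few genes, led by the skin-associated Mir203 and by members of the let-7 and Mir99 families. Reads set aside as mapping to several places equalled 60.1% of the assigned reads in replicate 1 and 65.3% in replicate 2. In each library 12 genes supplied 50% of the counts. Mir203, which lies at chromosome 12, 112130880 to 112130955, outside other genes on its strand, reached 79020 ± 16370 CPM (SD, n = 2). It was the most abundant gene of replicate 1, at 9.09% of counts (95% Clopper-Pearson interval 9.06 to 9.12), and took 6.72% (6.70 to 6.74) in replicate 2. In replicate 2 the most abundant gene was Mirlet7i, at 7.48% of counts (7.46 to 7.50). Mirlet7i overlaps an exon of D630033A02Rik at chromosome 10, 122985640 to 122985724, and averaged 70479 ± 6533 CPM (SD, n = 2). The means of Mir203 and Mirlet7i differed by less than the SD of Mir203, and their order was opposite in the replicates.

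**Figure D1:**
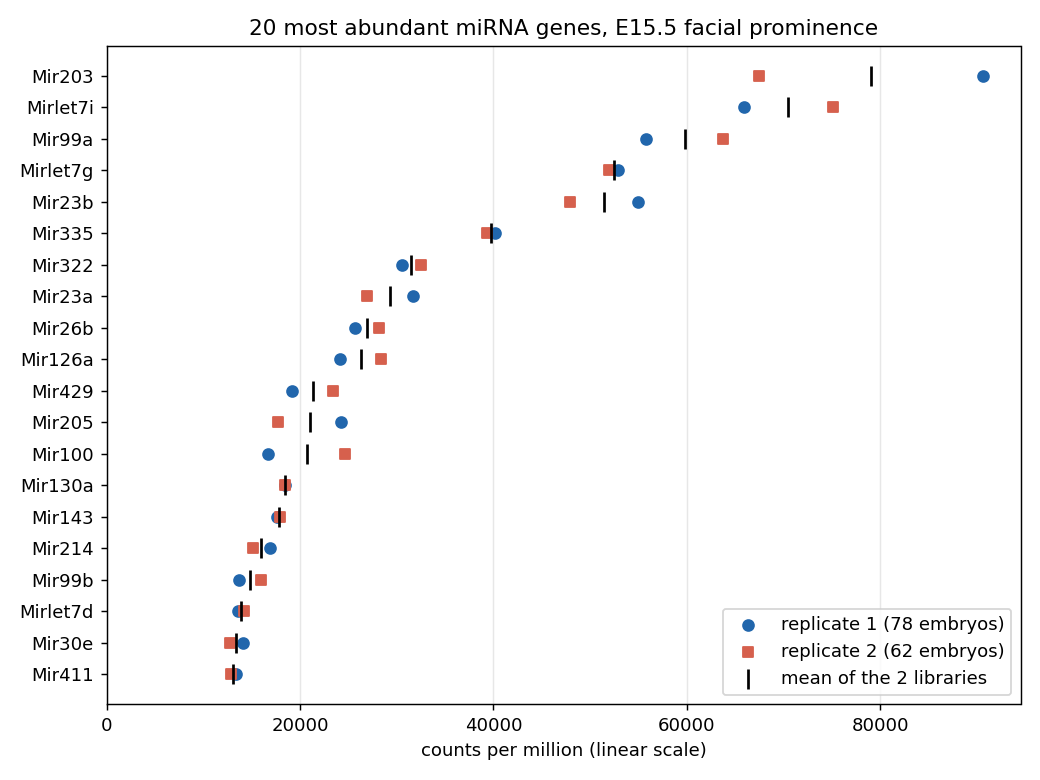
The 20 most abundant miRNA genes, with CPM on a linear axis, each replicate as a point and the mean of the 2 replicates as a vertical mark. Mir203 and Mirlet7i lead at 79020 and 70479 CPM, and Mir411 closes the list at 13107 CPM.

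The next most abundant genes included several that lie within protein-coding or long noncoding genes. Mir99a, in an intron of the noncoding gene Mir99ahg at chromosome 16, 77598936 to 77599000, reached 59776 ± 5631 CPM. Mirlet7g, in an intron of Wdr82 at chromosome 9, 106178840 to 106178927, reached 52439 ± 666 CPM, and Mir23b, in an intron of 2010111I01Rik at chromosome 13, 63300484 to 63300557, reached 51442 ± 4939 CPM. Mir335, in an intron of the imprinted gene Mest at chromosome 6, 30741299 to 30741396, reached 39738 ± 622 CPM. Mir322 on the X chromosome stood at 31509 ± 1378 CPM, Mir23a on chromosome 8, which shares sequence with Mir23b, at 29316 ± 3320 CPM and Mir26b, in an intron of Ctdsp1, at 26922 ± 1754 CPM. The endothelial Mir126a, which overlaps an annotated exon of Egfl7 at chromosome 2, 26591357 to 26591429, had 26285 ± 3011 CPM (all SD, n = 2). The remaining members of the top 20 ranged from 21303 ± 3037 CPM for Mir429 to 13107 ± 363 CPM for Mir411 (SD, n = 2).

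In reads mapped to 1 place, epithelial miRNAs were the most abundant of the tissue-type lists. The 7 epithelial genes, which include the Mir200 family that maintains epithelial identity, summed to 140261 ± 16606 CPM, or 14.03% ± 1.73 of counts (SD, n = 2). Mir203 supplied 56.3% of that sum, followed by Mir429 (21303 ± 3037 CPM), Mir205 (20992 ± 4643 CPM) and Mir200c (10424 ± 664 CPM). With Mir203 left out of the totals the sum was 66504 ± 262 CPM. The epithelial sum exceeded the cartilage sum 9.85-fold in replicate 1 and 8.87-fold in replicate 2, and the striated muscle sum 18.8-fold and 21.1-fold. No epithelial gene and 0 of 3 cartilage genes share a stretch of 20 bases with another hairpin, but 5 of 10 striated muscle, 3 of 6 mesenchyme and neural crest and 11 of 14 neural genes do, so ratios to these lists hold only for reads mapped to 1 place. The ciliated epithelium list of 6 genes summed to 11801 ± 4120 CPM, of which Mir449a, in an intron of Cdc20b on chromosome 13, made up 88.4%. The sensory cluster of Mir183, Mir182 and Mir96, known from the inner ear and retina, summed to 17523 ± 4057 CPM, with 7620 ± 1964 CPM for Mir183.

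The mesenchymal, cartilage, smooth muscle and endothelium lists had sums between 14955 CPM for cartilage and 26285 CPM for endothelium. The mesenchyme and neural crest list summed to 17696 ± 1025 CPM. Mir214, which overlaps an exon of the noncoding gene Dnm3os at chromosome 1, 162223368 to 162223477, supplied 90.3% of it. In this list 3 of 6 genes share sequence with another hairpin, so the 90.3% holds only for reads mapped to 1 place. The cartilage list summed to 14955 ± 670 CPM (SD, n = 2). Its main member, the cartilage miRNA Mir140, overlaps an exon of Wwp2 at chromosome 8, 107551244 to 107551313, and reached 12939 ± 334 CPM, while Mir455, in an intron of the collagen gene Col27a1, reached 1947 ± 340 CPM. Smooth muscle genes summed to 18054 ± 251 CPM, of which Mir143 made up 98.5%, while its neighbour Mir145a stood at 269 ± 28.0 CPM. The endothelium list held Mir126a alone.

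Striated muscle genes summed to 7092 ± 1417 CPM, and 97.0% of this came from Mir206, a miRNA of developing skeletal muscle, at chromosome 1, 20679010 to 20679082. The heart-associated Mir208b, in an intron of Myh7, stood at 84.9 ± 3.85 CPM, and Mir499, in an intron of Myh7b, at 46.2 ± 17.9 CPM. Of the 10 striated muscle genes 4 were at the floor and 5 share a stretch of 20 bases with another hairpin. The sum, the share of Mir206 and the genes at the floor therefore hold only for reads mapped to 1 place. Mir133b, 3687 bases from Mir206, had 75.5 ± 6.27 CPM and shares sequence with other Mir133 genes, so its value is uncertain.

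Neural, blood, pigment cell and organ-specific miRNAs were present at lower levels. The 14 neural genes summed to 757 ± 62.9 CPM, led by Mir137 (199 ± 7.65 CPM) and Mir128-1 (197 ± 54.8 CPM, or 343 ± 76.3 CPM with its copy Mir128-2 summed), 4 were at the floor and 11 share sequence with another hairpin. Erythroid genes summed to 233 ± 10.4 CPM with Mir451a at 139 ± 39.3 CPM. Leukocyte genes summed to 3861 ± 329 CPM, of which Mir342 made up 67.5%, and the myeloid Mir223 reached 510 ± 30.5 CPM. The counts of Mir142b in this list, 663 ± 62.3 CPM, came from the opposite strand. The pigment cell, retina and lens list summed to 311 ± 61.3 CPM, led by Mir204 (160 ± 59.3 CPM) in an intron of Trpm3. Liver, gut and pancreas genes summed to 2387 ± 646 CPM, 91.5% of it from Mir375, a miRNA of endocrine and other epithelia. In this list 2 of 9 genes share sequence with another hairpin. The liver miRNA Mir122 stood at 50.2 ± 28.0 CPM. Genes of pluripotent cells summed to 128 ± 17.3 CPM, with 5 of 12 at the floor and Mir302a highest at 43.3 ± 8.73 CPM. Among these 12 genes 4 share sequence with another hairpin.

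**Figure D2:**
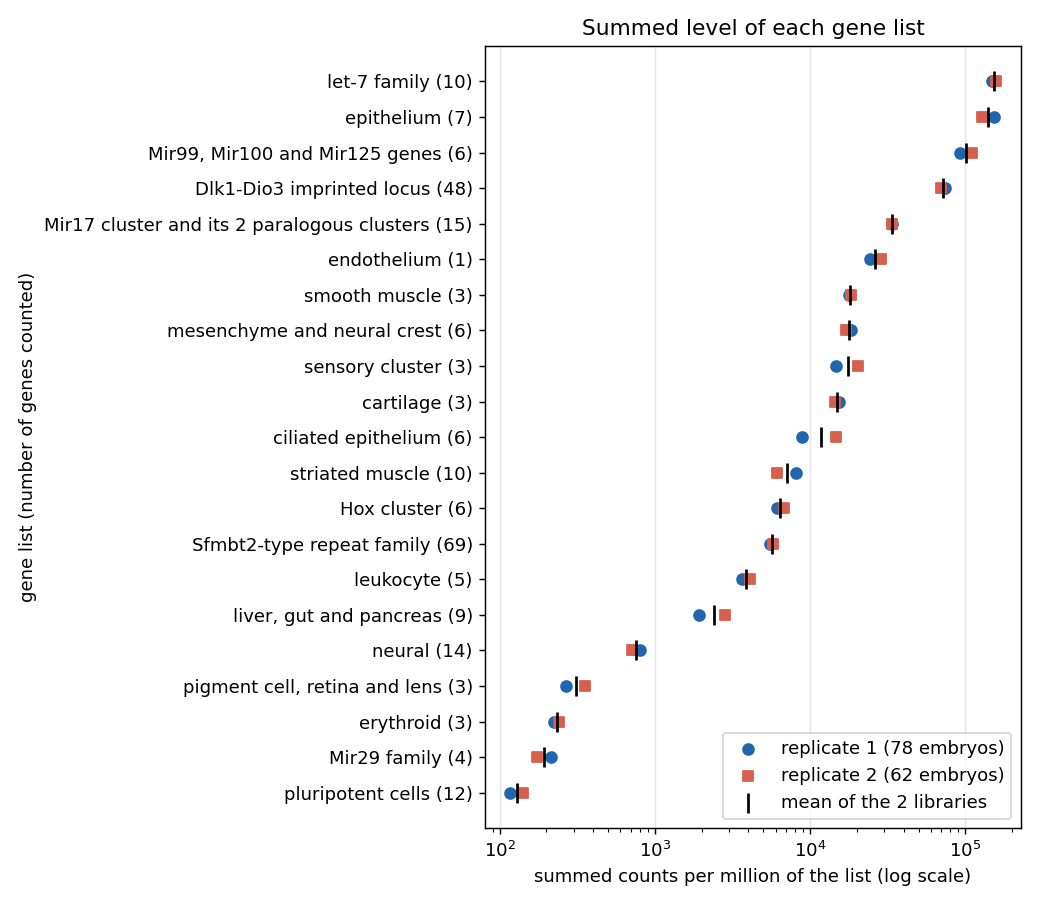
Summed CPM of each gene list on a log axis, with each replicate as a point, the mean as a vertical mark and the number of genes beside each name. The let-7 family (153358 CPM) and the epithelium list (140261 CPM) are highest and the pluripotent cell list (128 CPM) is lowest.

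Broadly expressed families and large clusters took much of the remaining counts. The 10 counted let-7 genes, which are known to accumulate in differentiating tissues, summed to 153358 ± 6494 CPM, or 15.3% ± 0.574 of counts. All were detected, although 5 of them share sequence with another hairpin and are uncertain. Mirlet7e and Mirlet7f-1 are not among the counted genes, so the let-7 sum leaves them out. The Mir99, Mir100 and Mir125 genes summed to 100902 ± 12928 CPM, and 2 of the 6 share sequence with another hairpin. The Mir17 cluster and its paralogous clusters, associated with proliferation, summed to 33926 ± 5.17 CPM, led by Mir17 (13014 ± 1350 CPM) and by Mir93 (6259 ± 269 CPM) within Mcm7. Of these 15 genes 4 share sequence with another hairpin. In the imprinted Dlk1-Dio3 locus on chromosome 12, 43 of 48 counted genes of the list were detected and the sum was 72058 ± 3378 CPM. Mir411 stood at 13107 ± 363 CPM, Mir487b at 9807 ± 1143 CPM and Mir127 at 8976 ± 1222 CPM. This sum leaves out at least Mir409, Mir376a and Mir380, which are not among the counted genes. The counted genes opposite them, Gm24321, Gm25252 and Gm25750, chosen after their values were seen, had 5262 ± 1336, 2850 ± 554 and 928 ± 78.0 CPM. All of these reads lay on the opposite strand, and they are not in the sum. Of the 48 counted genes of the list 4 share sequence with another hairpin. The counts of Mir299b in this locus, chosen after its values were seen, were 1793 ± 320 CPM and lay almost entirely on the opposite strand. Of the 69 genes of the repeat family typified by the Sfmbt2 intron, 55 were at the floor and 9 were detected. Their sum was 5652 ± 199 CPM, with Mir467d at 1863 ± 2.88 CPM, and 67 of them share sequence with another hairpin. Mir29 genes, linked to matrix gene control, summed to 194 ± 29.3 CPM, and 3 of the 4 share sequence with another hairpin, so this sum is uncertain. The Hox cluster genes summed to 6432 ± 487 CPM, 92.1% of it from Mir10b in an intron of Hoxd3 (all SD, n = 2). Of these 6 genes 2 share sequence with another hairpin, so the sum and the 92.1% hold only for reads mapped to 1 place.

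The libraries were then compared with each other to ask how far replicate pools of this tissue differ. Mir10a and Mir196b of the Hox clusters, Mir449a of ciliated epithelium and Mir96 of the sensory cluster were over 1.5-fold higher in replicate 2. Of 333 genes tested, 297 (89.2%) lay within 1.5-fold. These included Mir183 and Mir182 of the sensory cluster, which were higher in replicate 2, and Mir203, Mir205 and Mir206, which were higher in replicate 1. Across genes, which are not independent replicates, log2 CPM had a Pearson r of 0.992 and a Spearman rho of 0.993. The SD of the log2 ratio was 0.45 and its median size 0.20. The common dispersion in edgeR was 0.0297 ± 0.00523 (bootstrap SD over genes), a biological coefficient of variation of 17.2% ± 1.45. Against counting error only, the chi-square between the libraries was 200.3 per degree of freedom, so they were not treated as 1 library deposited again.

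The exact binomial test called 178 of the 333 genes, 86 higher in replicate 2 and 92 higher in replicate 1, and 186 had an unadjusted p under 0.05. Among the called genes, 25 differed by over 1.5-fold, 21 of them higher in replicate 2, and 12 differed by over 2-fold, 11 of them higher in replicate 2. Mir511, in an intron of Mrc1, was the 1 gene over 2-fold higher in replicate 1 (log2 ratio −2.10, 26 against 13 reads) and was chosen after its values were seen. With no residual degrees of freedom these calls compare the libraries and cover counting error only.

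**Figure D3:**
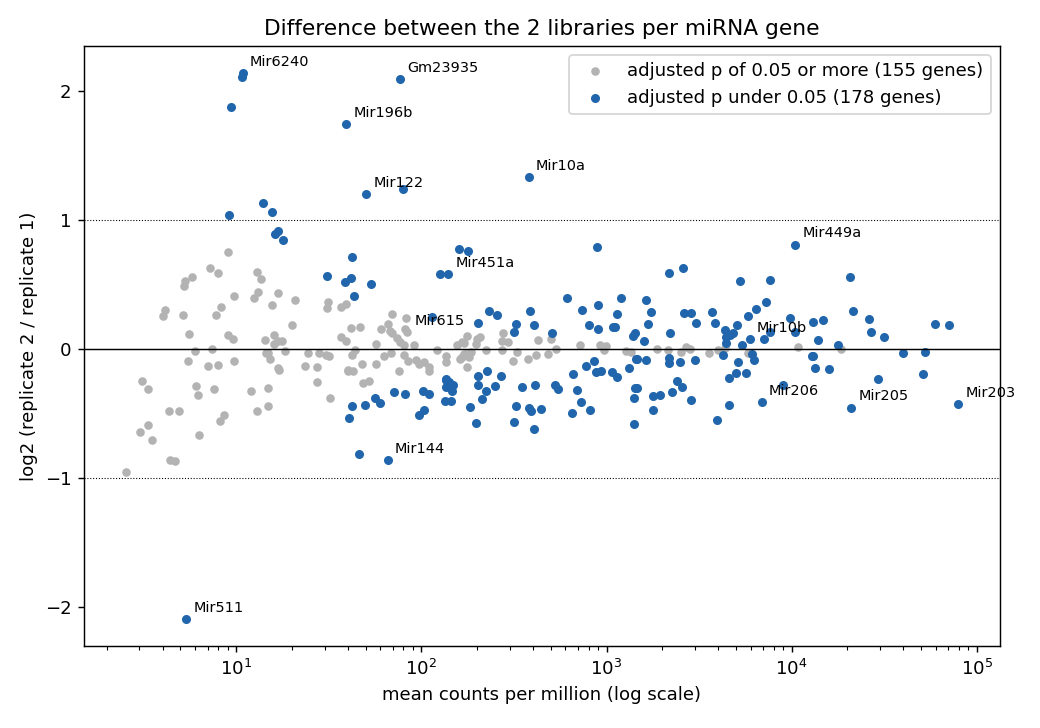
Log2 ratio of CPM in replicate 2 over replicate 1 against mean CPM on a log axis for the 333 detected genes, with called genes in blue and dotted lines at 2-fold. The scatter is centred near a median log2 ratio of −0.02, and Mir10a and Mir196b lie above it at 1.34 and 1.75.

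Among the Hox cluster genes, Mir10a and Mir196b stood apart, while the summed list differed by a log2 ratio of only 0.15. The median log2 ratio over the 4 tested members was 0.73, at percentile 99.7 of matched random lists. It fell in a gap between Mir10b and Mir615 below and Mir10a and Mir196b above. Of the 4 tested members, 3 were higher in replicate 2 and 1 did not pass. Mir10a, which lies outside other genes on its strand at chromosome 11, 96317165 to 96317274, was higher in replicate 2 by a log2 ratio of 1.34 (95% interval 1.21 to 1.46, 644 against 3474 reads, exact binomial adjusted p = 2.45e-124). Mir196b, which overlaps an annotated exon of Hoxa9 at chromosome 6, 52230081 to 52230165, had a log2 ratio of 1.75 (1.33 to 2.18, 54 against 387 reads, exact binomial adjusted p = 4.74e-21). Mir10b differed by 0.07 (0.05 to 0.10), and Mir615, in an intron of Hoxc5, had a ratio of 0.13 with an interval of −0.09 to 0.36 and was not called.

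Most ciliated and all sensory epithelial genes were also higher in replicate 2. In the ciliated list 4 genes were higher in replicate 2, 1 was higher in replicate 1 and 1 did not pass, against 5 and 1 when adjusted over the list alone, and the median log2 ratio of 0.58 lay at percentile 99.6. Mir449a had a log2 ratio of 0.81 (0.79 to 0.83), and Mir34a was the member higher in replicate 1 (−0.48, −0.58 to −0.38). All 3 sensory genes, which are neighbours on chromosome 6, were higher in replicate 2 with a median log2 ratio of 0.53. Their percentile of 99.0, like that of other lists of neighbouring genes, came from random lists that ignore linkage and does not allow for neighbours that vary together. Mir375 was higher in replicate 2 by 0.59 (0.54 to 0.63) and Mir122 by 1.20 (0.87 to 1.54), while the other 4 tested genes of the liver, gut and pancreas list did not pass. In the pigment cell, retina and lens list, Mir204 (0.77) and Mir184 (0.55) were higher in replicate 2 and Mir211 was not called (−0.17, −0.36 to 0.02), with a list median at percentile 96.2.

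The epithelial list was divided between the replicates. Mir203 (−0.43, 95% interval −0.43 to −0.42), Mir205 (−0.46, −0.47 to −0.44) and Mir200a (−0.15, −0.20 to −0.09, chosen after its values were seen) were higher in replicate 1, and the other 4 were higher in replicate 2, among them Mir429 (0.29, 0.28 to 0.31). Striated muscle had a median log2 ratio of −0.42 over 5 tested genes, at percentile 1.61. Mir206 (−0.42, −0.44 to −0.39) and Mir499 (−0.81, −1.11 to −0.52) were higher in replicate 1, and the other 3 were not called. In the Dlk1-Dio3 locus 21 genes were higher in replicate 1, 3 were higher in replicate 2 and 19 did not pass, and the median log2 ratio of −0.10 lay at percentile 4.78. Mir376c (−0.62, −0.72 to −0.52) and Mir154 (−0.58, −0.64 to −0.53) had the largest ratios of this locus among the named genes.

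The other lists with at least 3 tested genes had median log2 ratios between percentile 19.2, for the Mir17 clusters, and percentile 94.7, for mesenchyme and neural crest. Counts adjusted over the list alone equalled those over all genes except for the ciliated and leukocyte lists. Higher in replicate 2, higher in replicate 1 and not called were 5, 3 and 2 let-7 genes, 4, 0 and 2 Mir99, Mir100 and Mir125 genes, and 2, 6 and 7 genes of the Mir17 clusters. The same counts were 4, 1 and 1 for mesenchyme and neural crest, 0, 2 and 1 for cartilage, 0, 2 and 6 for neural genes and 3, 1 and 5 for the Sfmbt2-type repeats. Smooth muscle had 1 gene higher in each library. Mir29 genes had 1 higher in replicate 1 and 1 not called, and Mir126a was higher in replicate 2 (0.23, 0.22 to 0.25). For leukocyte genes 2 were higher in replicate 2, 1 was higher in replicate 1 and 2 did not pass, against 3 and 1 adjusted over the list alone. In the pluripotent list Mir302a was higher in replicate 2 (0.41, 0.10 to 0.74) and 3 genes did not pass. In the erythroid list Mir144 was higher in replicate 1 (−0.86, −1.11 to −0.61) and its neighbour Mir451a was higher in replicate 2 (0.58, 0.40 to 0.77).

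Among genes with at least 50 reads on average, 4 of the 5 largest ratios toward replicate 2 belonged to genes of low level outside the lists. Mir6240 (2.14, 1.28 to 3.13), Mir6538 (2.11, 12 against 111 reads), Gm23935 (2.10, 1.78 to 2.43) and Gm26117 (1.87, 1.00 to 2.88) were higher in replicate 2. Of these Gm23935 had the most reads, with 87 in replicate 1 and 795 in replicate 2, and shares sequence with other hairpins, while Mir6240 had 12 and 113. Toward replicate 1 the 5 largest ratios all belonged to members of lists, namely Mir144, Mir499, Mir376c, Mir154 and, of the neural list, Mir128-1. The last, in an intron of R3hdm1, had a ratio of −0.58 (−0.72 to −0.44) and shares sequence with Mir128-2. Mir130a had a log2 ratio of 0.00 with an interval of −0.01 to 0.02 and was not called, but was called at 0.02 with DESeq2 size factors.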

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

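All tests in this part, and the gene pairs compared, were chosen only after the result was seen.

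Several genes carried most of their reads on the strand opposite to their own annotation, in a column that the comparisons did not use by itself. Over both libraries these were 100938 reads opposite Gm25301, 56846 opposite Gm25927, 52541 opposite Gm24321, 36816 opposite Gm24083, 25383 opposite Gm25252 and 16011 opposite Mir299b. A further 8511 reads lay opposite Gm25750, 8037 opposite Mir497b, 6065 opposite Mir142b, 1261 opposite Gm24111 and 790 opposite Mir3074-1. Together these 11 genes held 99.9% of opposite-strand reads.

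A loss of strand information in the libraries was argued against, since 308 detected genes with no miRNA gene opposite had a median opposite-strand share of 0% and a highest share of 2.21%. A candidate explanation is that each such gene lies opposite a known miRNA gene that is not itself among the counted genes. Of the 11 genes, 11 overlapped one, against 32 counted genes with such an overlap in all (Fisher's exact test, p = 3.00e-21). No counted gene overlapped a counted miRNA gene on the other strand, so the condition of being uncounted could not fail. The background also held 1265 genes with no read in either library, so the p adds little to the 11 of 11. The opposite genes include Mir378a for Gm25301, Mirlet7e for Gm25927, Mir409 for Gm24321, Mir191 for Gm24083 and Mir142 for Mir142b. On this hypothesis the reads may come from those miRNAs, on whose strand they lie and whose own genes are not counted. In the either-strand counts these reads stand under the name of the counted gene, as for Gm25301 (10748 ± 75.7 CPM) and Gm25927 (6092 ± 109 CPM, SD, n = 2). At both of these genes 100% of the reads lay on the opposite strand. No biological explanation was tested.

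Reads that mapped to several places, which entered no gene, numbered 1789456 in replicate 1 and 4186211 in replicate 2. Hairpins that share 20 bases with another hairpin were detected in 75 of 929 cases (8.07%), against 258 of 965 (26.7%) of the others. The sharing hairpins include 67 of the 69 genes of the Sfmbt2-type repeat family, a family with 55 genes at the floor. This contrast therefore mixes repeat genes with other copies. Mir99a exceeded its neighbour Mirlet7c-1 301-fold, Mir206 exceeded Mir133b 91.1-fold, Mir214 exceeded Mir199a-2 79.3-fold and Mir100 exceeded Mirlet7a-2 75.6-fold. Whether these low counts come from reads set aside for matching several copies cannot be told apart from other causes: the sharing genes were lower in 18 of 23 genomic clusters with both kinds, but these include the 4 pairs that prompted the test, and without them it was 14 of 19 (two-sided exact sign test, p = 0.0636, median log2 difference −1.36). In 5 clusters they were higher, where their neighbours had a mean log2 (CPM + 1) of 0.34, 0.58, 0.66, 2.62 and 7.15. Where the neighbours had almost no reads, this direction says little about the sharing genes. Mir23a and Mir23b, which share sequence with each other, still reached 29316 and 51442 CPM, so a shared stretch alone does not set a low count. A shared stretch of 20 bases does not show that whole reads match both genes, so this pair does not decide the question. Processing or stability that differs between neighbours also stays open as untested.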

How the results depend on the processing

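No paired analysis was possible because the study has a single group. No test was added after the results were seen in this part. The number of genes called stayed between 162 and 186 under every alternative except the opposite-strand column. Without a filter on low counts 708 genes had a read, and with at least 100 reads in each library the dispersion was 0.0209, both following from the genes that enter. The opposite-strand column, which holds few genes, gave 14 detected genes, 9 called, a dispersion of 0.0171, a top share of 32.3% and 2 genes for 50% of counts, and Mir203, with few reads there, reversed to 0.87 in it. The cause was not tested. With one library left out, detected genes ranged from 333 to 409, the top share from 7.48% to 9.09% and the genes for 50% of counts from 12 to 12, and no test between libraries was possible. Log2 ratios near 0 changed sign with small shifts of scale: Mir130a (−0.0072) and Mir467d (−0.0069) with total counts, Mir125a (0.0103) and Mir338 (0.0097) with DESeq2 size factors, Mirlet7g (0.00049), Mir125a (0.0183) and Mir338 (0.0177) with at least 100 reads, and Mir125a (0.0024) and Mir338 (0.0018) with copies summed. Among these Mirlet7g had passed the threshold with TMM, and was also no longer called with DESeq2 size factors (−0.0075), nor Mir335 with at least 100 reads (−0.0056). Mir130a, Mir155 and Mir34b became called with DESeq2 size factors (0.0213, 0.289 and 0.371) and with at least 100 reads, and Mir155 with copies summed (0.281). Apart from the opposite-strand column, the log2 ratios of the other named genes kept their direction and their side of the threshold wherever they were computed. Depth limits the genes near 10 reads in replicate 1, the shallower library. With Mir203 left out of the totals, the 87 other named genes with a read (Mir145b had none) and the 20 list sums without it were higher by 1.09 times through the smaller total, and the epithelial sum was lower at 66504 CPM. By more than 1 SD, 3 list sums and 14 named genes moved with the own-strand column (12 of these genes higher), and 3 genes were higher with copies summed, Mir128-1 and Mir128-2 at 343 CPM (1.75 and 2.34 times their own levels) and Mir29b-2 at 2.39 CPM (5.08 times, near the floor). Leaving out 1 of 2 libraries moves a mean by a nearly fixed part of its SD, so the SD gives no measure of stability there. Levels of 9 named genes then lay over 1.5 times from the mean, Mir29b-1 and Mir29b-2 near the floor and Mir10a (216 to 542 CPM), Mir122 (30.6 to 69.8), Mir196b (18.1 to 60.4), Gm23935 (29.2 to 124), Mir6240 (4.03 to 17.6), Mir6538 (4.03 to 17.3) and Gm26117 (4.03 to 14.7). The own-strand column took the Mir142b count to 0 and left 170 genes called.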

Other observations

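Of the tests in this part, those of Mir615 and of genomic clusters were chosen only after the result was seen, as were the families in the next paragraph.

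Other families outside the fixed lists were also abundant in reads mapped to 1 place. The Mir23, Mir24 and Mir27 genes, which lie in paralogous clusters, summed to 85545 ± 9435 CPM, and the Mir322 cluster on the X chromosome to 39873 ± 2283 CPM with Mir351 at 6377 ± 959 CPM. The Mir26 family summed to 26970 ± 1752 CPM, the Mir130 and Mir301 family to 22615 ± 236 CPM and the Mir30 family to 22209 ± 1073 CPM. Lower sums were found for the Mir181 family (9639 ± 571 CPM), the Mir15 and Mir16 family (6116 ± 27.5 CPM) and the Mir148 and Mir152 family (1673 ± 83.0 CPM, all SD, n = 2). Nearly all of the Mir26 sum came from Mir26b, at 26922 CPM. Its relatives Mir26a-1 and Mir26a-2, which share sequence with another hairpin, had 8.30 and 40.1 CPM. Some genes of the Mir23, Mir24 and Mir27 set and of the Mir30, Mir181 and Mir15 and Mir16 families also share sequence. The sums of these families and their order are therefore uncertain. Mir27b was higher in replicate 1 by a log2 ratio of −0.55, and Mir351 was higher in replicate 2 by 0.31.

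Mir10a and Mir196b, both in Hox clusters, were higher in replicate 2 by log2 ratios of 1.34 and 1.75. A linear trend of the ratios with hairpin GC content was argued against as the whole cause. After removal of this trend, fitted over 331 other genes (Spearman rho 0.0924, permutation p = 0.0922), the ratios were 1.41 for Mir10a and 1.76 for Mir196b. The residual SD was 0.43. GC content was taken over the whole hairpin and not over the sequenced fragments, so a GC bias of the fragments stays untested. More tissue from a Hox-expressing region in replicate 2 may contribute and cannot be told apart from other causes. Mir615 had a ratio of 0.13 (−0.09 to 0.36), with an upper bound below the lower bounds of Mir10a (1.21) and Mir196b (1.33). This could count against the explanation only in genes with no other source, and Mir10b and Mir615 have their own level in the tissue. Mir196a-2, chosen after its values were seen, had 8 and 56 reads and was below the filter.

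A hypothesis that neighbouring miRNA genes vary together between the pools was tested on 150 genes in 42 genomic clusters. The mean variance of the log2 ratio within clusters was 69.5% of that in permuted genes (one-sided permutation p = 0.0203). Without the biggest cluster, 29 genes on chromosome 12, it was 65.0% over 121 genes in 41 clusters (permutation p = 0.00578). Some per-gene ratios had been seen before this test was chosen, and their clusters were not left out. The permutation also did not match genes on read depth. These values therefore describe the libraries and do not decide the hypothesis. Mir144 (−0.86) and its neighbour Mir451a (0.58) went in opposite directions.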
